A study of Homo sapiens with 3 samples.

How the data were processed

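H1299 cells, an established human line of non-small cell lung cancer, were profiled by CUT&RUN. In this assay an antibody directs a nuclease to its target in intact nuclei, and the DNA cut free around the target is sequenced. The series holds 3 libraries, 1 each with an antibody against the transcription factor SP1, an antibody against acetylated lysine 27 of histone H3 (H3K27ac, a mark of active promoters and enhancers) and a control IgG. Files of the SP1 and H3K27ac libraries were used. The IgG library was not analysed here, so no background of that kind stands beside any value.

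For each of the 2 antibodies the authors deposited a list of peak summits, each a single base with a score, and a list of ranked regions. The score in the deposited summit lists is the peak caller's −log10 of a p-value or q-value. The files do not say which of these it is. The lowest score lay just above 3 in both lists, which corresponds to a threshold of 0.001. A deposited region carries its start, its end, the number of peaks joined in it and its rank, but not the signal it was ranked on. Item names in the files have the form that MACS and ROSE write. Per the submitters' processing notes, coordinates are those of hg38, and cutadapt 2.5 and deepTools 3.4.1 were used, with no role stated. The aligner, the peak caller with its settings, any control used in calling and any merging of reads are not given in the sources used here. The files hold no read counts, so the sequencing depth of each library is unknown. A different depth or a different control in calling would change how many summits each list holds, so numbers of summits were not compared between antibodies as amounts of binding.

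Genes came from a RefSeq table of the same assembly (GRCh38.p14), with 20037 protein-coding genes on the 24 chromosomes of the files. The table gives each gene's span without its strand, and no genome sequence was used here. The planned promoter measure, within 1000 bases of a transcription start site, was therefore replaced by a position within 1000 bases of either end of a protein-coding gene span, called a gene end below. A gene end can be the start or the end of a gene, and alternative start sites inside a gene are missed. The planned counts of GC boxes, the DNA element that SP1 binds, were not run for lack of sequence. Coordinates are given 1-based.

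Shares of summits or regions are given with 95% Wilson intervals. These cover counting error only and treat summits as independent. Each share stands beside 1000 random placements, in which every summit or region was moved to a random position on its own chromosome with its length kept. Shares by region rank stand beside 200 placements, and the shares in gene spans and the clustering in the closing section beside 100. Placement took no account of sequence that reads cannot be mapped to. Overlap of regions needed at least 1 base, and summits of the 2 libraries within 500 bases of each other were called shared. With 1 library per antibody there are no replicates, so no p-value was computed and nothing measures the spread between cultures. Scores were compared only within a list, apart from a rank correlation over shared summits in the closing section. Differences of median scores have bootstrap intervals from 1000 draws of summits.

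For 15 gene lists fixed before the data were examined, the number of members with a summit at a gene end was placed among 10000 random lists of the same size drawn from the protein-coding genes, with ties counted as 50%. Older symbols were matched through the table's synonyms. The genes named are those of a rule fixed before the data were examined: RGS20, the 10 best-ranked regions and the 10 highest summits of each library with a gene whose end lies inside or the nearest one, and from each list up to 4 members with summits of both libraries and up to 2 with a summit of 1 library, highest score first. Where a list had none, its first 2 members are named. Some genes that the rule names are not reported here. Genes outside this rule are marked as chosen after their values were seen.

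The calculations were tested on simulated data. With 0%, 5% and 30% of an SP1-sized set of 5570 summits planted at gene ends, the share above random placement came to 0.218%, 4.69% and 29.3%. Planted in H3K27ac regions, it came to 0.0869%, 4.97% and 30.0%. Of 500 random lists of 20 genes, 1.4% lay above the central 95% of lists and 4.6% below it, where 2.5% are due on each side. A first version of this test, which required few lists outside both limits, failed. A list of that size with no hit falls near the lower limit, although about 5% of random lists have none. Low percentiles were therefore not used to single out a list, and the share of random lists with no hit is given in their place. Alternatives fixed before the data were examined covered stricter scores, other distances and windows, the better-ranked 50% of regions, overlap of at least 50% of a region and random placement within 100 kb. Further ones were added afterwards, and the closing section gives their effect. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.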

Results

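The data describe where SP1 and H3K27ac were called in H1299 cells. The SP1 list held 5570 summits, with a median score of 6.17 and a highest score of 268. The H3K27ac list held 3201 summits, with a median score of 5.01 and a highest score of 275. Scores above 10 were reached by 20.4% of SP1 summits and by 2.06% of H3K27ac summits, 66 in number. The ranked regions numbered 2356 for SP1 and 2710 for H3K27ac, and 96.6% and 96.4% of them consisted of 1 peak. They covered 1071 kb and 1379 kb. The region lists held few of the summits near genes. Of 2775 SP1 summits within 2500 bases of a gene end, 5.01% lay in an SP1 region, against 82.8% of the other 2795. For H3K27ac the shares were 31.5% of 254 and 93.2% of 2947. There was 1 library per antibody, so no value below has a replicate.

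The first comparison asked where the summits of each library lay relative to genes. SP1 summits were concentrated at gene ends. Of the 5570 summits, 2457 were within 1000 bases of a gene end, or 44.1% (95% Wilson interval 42.8 to 45.4), against a mean of 3.21% and a maximum of 4.04% over 1000 random placements. H3K27ac summits were seldom there. Of 3201 summits, 150 lay at a gene end, or 4.69% (4.01 to 5.47), against a random mean of 2.47% and a maximum of 3.44%. The SP1 share was thus 13.8-fold above random placement and the H3K27ac share 1.90-fold. Placed only within 100 kb of their own position, an alternative chosen after seeing the data, SP1 summits stood 6.74-fold and H3K27ac summits 1.78-fold above random. Without gene-distant positions, also chosen then and defined in the closing section, the H3K27ac share was 7.53% and 2.93-fold above random. This rise is set by the filter, since all 150 summits at gene ends stayed and only others were removed. Random positions could still fall anywhere on the chromosome.

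The 2 lists also differed in how position went with score. In the lowest-scoring 557 SP1 summits, 14.4% were at a gene end (11.7 to 17.5). This share was 33.4% in the fifth group of 557 by score and 75.9% in the highest-scoring group (72.2 to 79.3). Among H3K27ac summits the share lay between 2.81% and 7.19% in every group of 320 or 321, and it was lowest in the highest-scoring one.

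**Figure D1:**
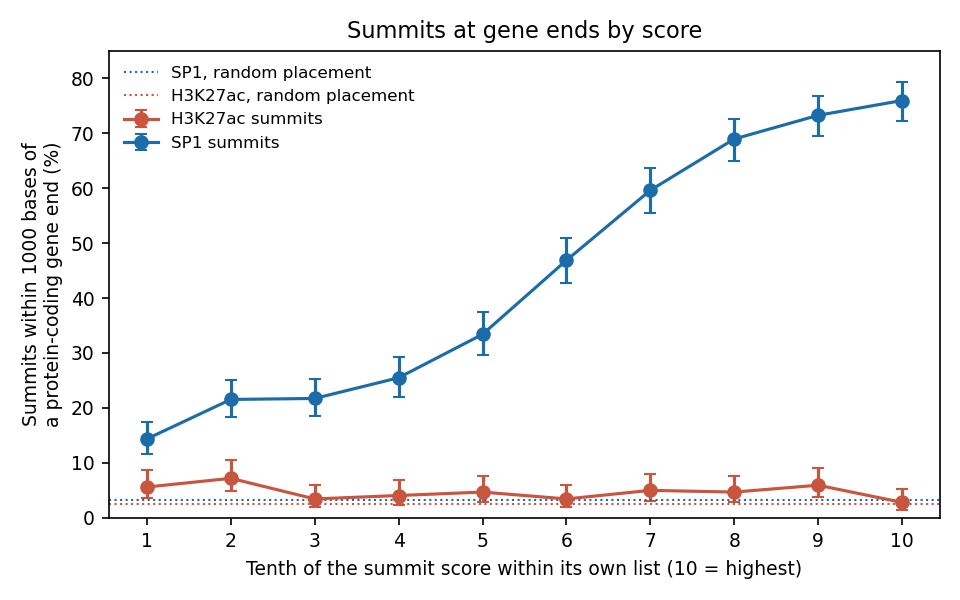
Share of summits within 1000 bases of a protein-coding gene end (percent) against the group by score within each list, from 1 (lowest) to 10 (highest), with 95% Wilson intervals as bars and the mean of random placements as dotted lines. The SP1 share climbs from 14.4% to 75.9%, while the H3K27ac share stays between 2.81% and 7.19%.

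At the level of genes, 2752 of 20037 protein-coding genes (13.7%) had an SP1 summit at an end. H3K27ac summits were found at 170 genes (0.848%). Both were found at 34 genes, where 23.3 would be expected if the gene sets were independent. Neighbouring genes with the same summits were each counted, and the 2 summits of a gene could lie at different ends. Genes are thus not independent units here, and the excess has no interval. Shared SP1 summits at a gene end numbered 19. Among the 34, HSPA1B, which encodes an inducible heat shock protein, had the highest SP1 score, 18.4, at 495 bases from its low-coordinate end, and an H3K27ac score of 5.10 at 820 bases from its other end. JAG1, a Notch ligand gene, had an SP1 score of 9.33 at its high-coordinate end and an H3K27ac score of 4.63 at its low-coordinate end. The neighbouring genes CDC45, needed to start DNA replication, and UFD1 had the same pair of summits, with scores of 9.11 and 5.99. EIF3B, a translation initiation factor gene, and its neighbour SNX8 had summits of 10.9 and 14.8. RPL41, a ribosomal protein gene, had 10.5 at its low-coordinate end and 7.47 at its high-coordinate end. These genes were chosen after their values were seen.

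Among the 15 gene lists, the cell cycle and replication list stood above the central 95% of random lists for SP1. Of its 25 members, 8 had an SP1 summit at an end, against a random mean of 3.42, which is the 99.05th percentile. The highest-scoring were MCM3, part of the replicative helicase, with 11.2 at 497 bases from its end, and CCND3, a G1 cyclin gene, with 11.1 at 654 bases. The list fell to percentile 96.1 with a window of 500 bases and to percentile 95.7 with summits above the upper quartile of the score. No other list stood above the central 95%. With 15 lists compared, 1 list above that limit can arise by chance.

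Genes of general transcription and growth carried SP1 summits at numbers within those of random lists. Textbook SP1 targets had 4 of 18 members (84.2nd percentile), among them SP1 itself with a score of 25.7. Coactivators and RNA polymerase II machinery also had 4 of 18 (84.2nd percentile), with POLR2A, the largest subunit of the polymerase, at 21.6 and the bromodomain gene BRD3 at 10.5. AP-1 had 3 of 12 (85.2nd percentile), with FOS at 12.1 and FOSB at 10.9. The percentile of AP-1 was 99.7 with a window of 2500 bases. Ribosomal proteins had 6 of 33 (77.3rd percentile), led by RPS19 at 45.5 and RPL18 at 8.99. Oxidative phosphorylation had 3 of 21 (56.0th percentile), with CYC1 at 8.86 and UQCRC2 at 7.78.

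Genes recurrently altered in lung adenocarcinoma had 4 of 25 members with an SP1 summit (65.0th percentile), among them the receptor gene ERBB2 at 9.66. The mesenchymal list had 2 of 16 (48.3rd percentile), among them SNAI1 at 9.88. The list of TEAD, RUNX, SMAD and other growth-signal transcription factors had 2 of 21 (31.6th percentile), TEAD2 at 31.0 and HMGA1 at 6.08. The alveolar and airway list had 1 of 15 (24.0th percentile), NAPSA at 6.69, which encodes an aspartic protease of alveolar cells.

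No member of 5 lists had an SP1 summit at an end. These were the RGS family (0 of 21, which allows a share of up to 15.5% by the Wilson interval), epithelial junction and keratin genes (0 of 16), and markers of blood cells (0 of 16), neurons and glia (0 of 14) and hepatocytes (0 of 14). Random lists of the same size had none in 4.49%, 9.40%, 9.40%, 12.6% and 12.6% of draws. Neither RGS1 nor RGS2 had a summit of either library at an end, nor did the junction genes CDH1 and EPCAM, the leukocyte genes PTPRC and CD3D, the synaptic genes SYN1 and SNAP25 or the liver genes ALB and APOA1. No member of any of the 15 lists had an H3K27ac summit at an end. Random means were 0.105 to 0.277 members per list, so these counts of 0 separate no list from chance.

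The second comparison asked how far SP1 and H3K27ac lay at the same places. Few positions were shared, yet far more than by random placement. The region lists left out most summits near gene ends, as given above, which limits every share that uses regions. The share of SP1 summits near an H3K27ac summit does not depend on those lists. Of 5570 SP1 summits, 88 lay in an H3K27ac region, or 1.58% (1.28 to 1.94), against a random mean of 0.0579% and a maximum of 0.180%. Of 3201 H3K27ac summits, 78 lay in an SP1 region, or 2.44% (1.96 to 3.03), against 0.0422% and a maximum of 0.219%. Overlapping regions numbered 79 on each side, which was 3.35% of SP1 regions (2.70 to 4.16) and 2.92% of H3K27ac regions (2.35 to 3.62). An H3K27ac summit lay within 500 bases of 134 SP1 summits, or 2.41% (2.03 to 2.84), against a random mean of 0.118%. These shares were 20.4-fold to 57.7-fold above the random mean. Placement within 100 kb lowered the excess to 13.6-fold to 22.4-fold. Within 2000 bases in place of 500, SP1 summits lay near an H3K27ac summit 6.95-fold above random. Without gene-distant positions the share of SP1 summits in H3K27ac regions was 0.655% and 11.0-fold above random. That of H3K27ac summits in SP1 regions was 32.4-fold above it, and that of SP1 summits near an H3K27ac summit 18.7-fold. For the 2 shares in regions, gene-distant summits were removed but all regions were kept as targets. For summits near each other, both lists were filtered. Random positions could still fall anywhere on the chromosome, so these folds cannot be set against each other.

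**Figure D2:**
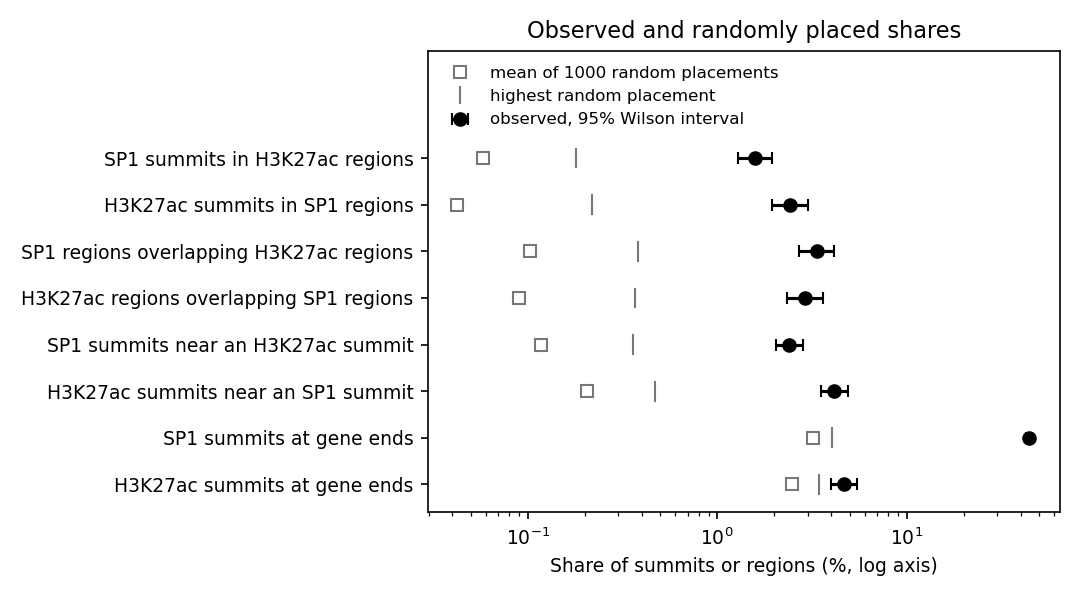
Observed shares (percent, log axis) with 95% Wilson intervals, beside the mean and the highest value of 1000 random placements, for overlaps between the libraries and for summits within 1000 bases of a gene end. All observed shares lie above the highest placement, from 1.58% against 0.180% for SP1 summits in H3K27ac regions to 44.1% against 4.04% for SP1 summits at gene ends.

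Over all positions, summits that coincided with the other library scored higher than others within each list. SP1 summits inside H3K27ac regions had a median score of 7.71 (quartiles 5.72 and 14.7) and those outside 6.16 (4.76 and 8.99). H3K27ac summits with an SP1 summit within 500 bases had a median of 6.93 (5.37 and 14.3) and the others 4.95 (4.24 and 5.89). For SP1 this was not seen without gene-distant positions. The 31 SP1 summits then left inside H3K27ac regions had a median of 6.13 against 6.64 outside, a difference of -0.513 (bootstrap 95% interval -1.15 to 1.37). The difference for H3K27ac then fell from 1.98 to 0.759 (0.0900 to 1.05). This setting also raised the share of SP1 summits at gene ends, which scored higher, to 51.9%, and the 2 effects were not separated. Among SP1 summits over 1000 bases from a gene end, gene-distant ones included, the difference was 2.57 (1.39 to 3.95). The very highest summits were common to both lists. All 10 of the highest SP1 summits and 9 of the 10 highest H3K27ac summits were shared, and none of these lay at a gene end. This did not extend far down the SP1 list. Of the 40 highest SP1 summits 17 were shared and 16 lay at a gene end, while of the 40 highest H3K27ac summits 35 were shared and 1 lay at a gene end.

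The highest summit in both lists was on chromosome 1 at position 125183762 in SP1 and 125183763 in H3K27ac, with scores of 268 and 275. Its nearest protein-coding gene in the table, LINC02798, was 3720633 bases away. The next was on chromosome 16 at 46390716 in both lists, with scores of 226 and 224 and SHCBP1 as nearest gene, at 187875 bases. On chromosome 17, SP1 summits at 26881402, 26603884 and 25920217 had scores of 193, 133 and 108, and WSB1 was the nearest gene at 412712 bases or more. The SP1 summits on chromosome 16 at 34588203, nearest to LOC124903767, and on chromosome 21 at 8234508, nearest to LOC102723475, had scores of 107 and 105. The remaining 3 of the 10 lay beside copies of mitochondrial DNA in the nuclear genome. Those at 134927674 and 134928305 on chromosome 5, inside PCBD2, scored 79.3 and 66.4. They lay within 1000 bases of pseudogenes that include MTND4P12. The third, at 634222 on chromosome 1 inside LOC102724250, scored 65.3 and lay within 1000 bases of pseudogenes that include MTCO2P12 and MTATP6P1. H3K27ac summits at 630435 and 633101 in the same stretch scored 75.2 and 70.3.

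Rank among H3K27ac regions went with SP1. Of the 271 best-ranked regions, 55 held an SP1 summit, or 20.3% (15.9 to 25.5), against a random mean of 0.603%. In the next 271 the share was 2.21%, and over all 2439 regions below the best 271 it was 0.697%. The best-ranked regions were also longer, with a median of 522 bases against 331 in the next group. Per 10 kb of region there were 0.941 SP1 summits in the best-ranked 271 and 0.272 in the rest, so the ratio between them fell from 29.1 to 3.45 when length was counted. Without gene-distant regions, 19 of the 145 best-ranked ones left held an SP1 summit, or 13.1% (8.55 to 19.6), against 9 of 1476 in the rest (0.610%). Per 10 kb the values were then 0.702 and 0.238 SP1 summits, a ratio of 2.94. The second group by rank held 0.669 SP1 summits per 10 kb over all its regions (6 summits) and 0.712 without gene-distant ones (4 summits). Counted by length, it thus stood much nearer to the best-ranked group than by share, though on few summits.

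**Figure D3:**
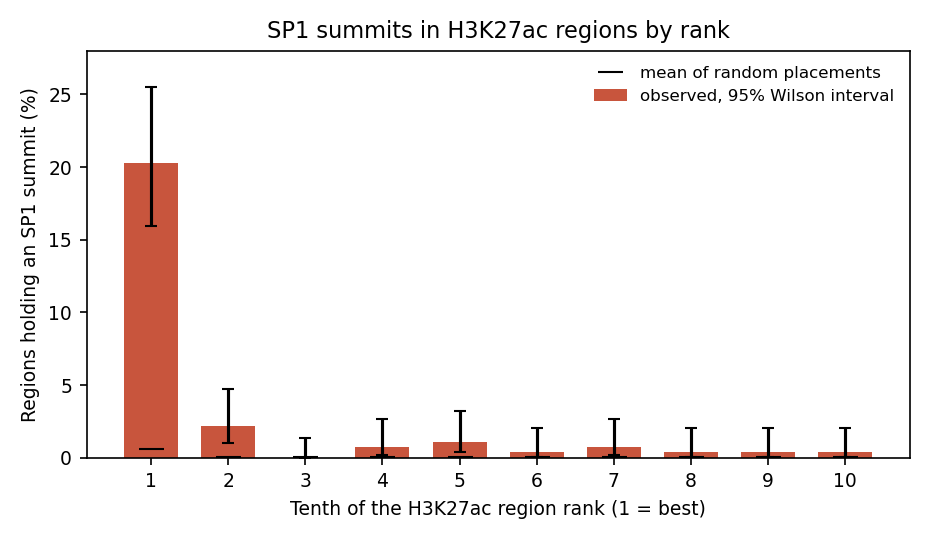
Share of H3K27ac regions holding an SP1 summit (percent), in 10 groups of 271 regions from the best rank (1) to the lowest (10), with 95% Wilson intervals and the mean of 200 random placements as dashes. The first group stands at 20.3%, the second at 2.21% and the others at 1.11% or less.

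The best-ranked regions of the 2 lists fell into separate kinds. Of the 10 best SP1 regions, 5 overlapped an H3K27ac region, and all of these were over 100 kb from any gene end. Their nearest genes were SHCBP1, WSB1, LINC02798, LOC124904970 and DEFB115, at distances from 187677 bases (SHCBP1) to 3720437 bases (LINC02798). The other 5 were on chromosome 19 and overlapped genes. The first, at 40420844 to 40433382, held an end of SERTAD1, a cell cycle regulator gene. The second, at 45443014 to 45456398, held an end of ERCC1, a DNA repair gene. The remaining ones were at PRR36, LTBP4, which encodes a TGF-beta binding protein of the matrix, and ETV2. Chromosome 19 held 11.3% of SP1 summits, 2.34% of H3K27ac summits and 7.24% of protein-coding genes.

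Of the 10 best H3K27ac regions, 8 overlapped an SP1 region, and 5 of these were the places shared with the best SP1 regions. A further one had KCNJ18 as nearest gene, at 110732 bases. The region on chromosome 12 at 75943914 to 75954077 had PHLDA1 as nearest gene, at 71370 bases. The region on chromosome 10 at 32971460 to 32982386 had ITGB1, an integrin subunit gene, at 13230 bases. The 2 regions with no SP1 region lay inside genes. One, on chromosome 14 at 68140143 to 68146944, was in RAD51B, a recombination gene. The other, on chromosome 17 at 59783712 to 59787171, was in VMP1, an autophagy gene.

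The title of the series names RGS20, which encodes a regulator that speeds the GTPase activity of G protein alpha subunits, together with SP1 and super-enhancers. RGS20 spans 53851795 to 53959303 on chromosome 8. Inside it lay 3 H3K27ac summits, at 53944963, 53945418 and 53946201, with scores of 9.15, 5.69 and 7.64. They formed 1 region of 1462 bases, from 53944875 to 53946336, ranked 61 of 2710, within the best 2.25% of the list. Whether this part of the gene is intron or exon cannot be read from gene spans. No SP1 summit was called within the gene span or the region. The nearest to the region was 76.3 kb away at 54022623, with a score of 11.7, and lay 175 bases from an end of TCEA1, a transcription elongation factor gene. On the other side, summits of both libraries lay at 53780095 (SP1, 5.78) and 53780083 (H3K27ac, 5.76), about 71.7 kb outside the gene. The files hold called summits and not coverage, so signal below the calling threshold cannot be seen.

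**Figure D4:**
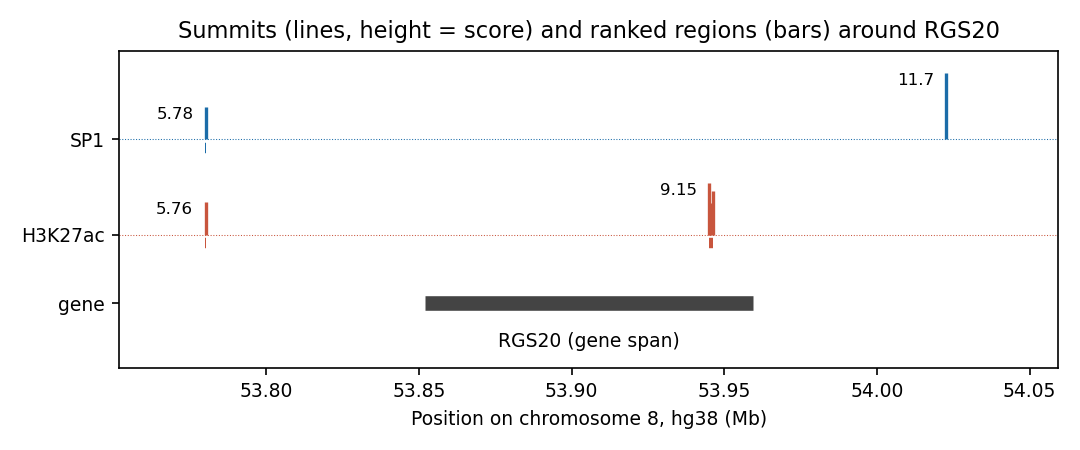
Map of chromosome 8 (hg38, position in Mb) around RGS20 with H3K27ac and SP1 summits as lines whose height is the score within each list, ranked regions as bars under the lines, and the gene span in grey. The 3 H3K27ac summits with scores up to 9.15 lie inside the gene, and the SP1 summits of 5.78 and 11.7 lie outside it.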

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

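No paired analysis was possible because there was 1 library per antibody. Of 91 alternative values other than list percentiles, 66 moved, 1 changed sign and 24 did neither, meaning that they stayed within the 95% interval of the main value (counts and the ratio by rank, within 1.5 times). Of 60 list percentiles, 57 stayed on their side of the upper limit of the central 95%, but below it they moved freely, such as ribosomal proteins from 77.3 to 25.5 with summits above the upper quartile and the alveolar list from 24.0 to 68.8 with a window of 2500 bases. No excess over random placement turned into a deficit. GC boxes and the choice of 1 start site per gene were not run, since they need sequence or strand. The settings without gene-distant positions (over 100 kb from a gene end, or within 1000 bases of an rRNA gene or mitochondrial pseudogene), with genes of every kind, and local placement for gene ends were added after seeing the data. Except where a narrower or wider window, fewer summits or region length moves a value by construction, the cause was not tested. Depth is unknown, and so is what it limits.

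With summits above the median score, the share of SP1 summits in H3K27ac regions was 1.98%, of H3K27ac summits in SP1 regions 4.38%, and of SP1 summits at gene ends 64.9%. H3K27ac was then at the ends of 82 genes and both libraries at 13. Above the upper quartile the 3 shares were 2.58%, 7.63% and 73.2%, and 3.30% of SP1 summits lay near an H3K27ac summit. SP1 was at 1244 genes, H3K27ac at 46, both at 5, and 0 gene lists stood above the central 95%. With the better-ranked regions, 5.09% of SP1 and 4.43% of H3K27ac regions overlapped. With 50% of the region covered, 1.88% of H3K27ac regions did. SP1 summits near an H3K27ac summit were 1.85% within 200 bases and 3.27% within 2000 bases, while the excess over random went the other way, from 39.0-fold to 6.95-fold.

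A window of 500 bases gave 36.5% of SP1 and 2.22% of H3K27ac summits at gene ends, 81 genes with H3K27ac, 13 with both and 0 lists. A window of 2500 bases gave 49.8%, 7.94%, 298 genes, 66 genes and 2 lists. Ends of genes of every kind gave 50.6% and 10.1%. The excess fell in both settings, to 6.77-fold and 6.95-fold for SP1 and to 1.38-fold and 1.61-fold for H3K27ac. Without gene-distant positions, 51.9% of SP1 and 7.53% of H3K27ac summits were at gene ends, a rise that the filter makes by construction. The shares were then 0.655% for SP1 summits in H3K27ac regions, 1.41% for H3K27ac summits in SP1 regions and 1.44% for SP1 summits near an H3K27ac summit. SP1 summits in H3K27ac regions scored 1.55 above the others (bootstrap 95% interval 0.415 to 3.04), and H3K27ac summits near an SP1 summit 1.98 (1.22 to 2.96). Away from gene ends the differences were 2.57 and 2.93, and with any summit of the other library within 2000 bases 0.952 and 1.62. Without gene-distant positions they were -0.513 (-1.15 to 1.37), a change of sign within its interval, and 0.759 (0.0900 to 1.05). Counted per 10 kb, the best-ranked H3K27ac regions held 3.45 times the SP1 summits of the rest, against 29.1 times as a share of regions. Without gene-distant regions, 13.1% of the best-ranked ones held an SP1 summit, 21.5 times the share in the rest.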

Other observations

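All tests here were chosen after the results were seen, except the 2 on H3K27ac summits near gene lists, and the gene groups and regions in the next 2 paragraphs were also chosen afterwards.

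Zinc-finger genes with the symbol ZNF carried SP1 summits at an end in 127 of 517 cases, or 24.6% (21.1 to 28.5), against a random mean of 70.9 genes. Among the highest were ZNF808 and ZNF524. Much of this went with chromosome 19. There, 31.2% of 250 ZNF genes and 30.2% of all protein-coding genes had an SP1 summit, while elsewhere it was 18.4% of 267 ZNF genes and 12.5% of all genes. Proteasome subunit genes had 13 of 50 (26.0%, random mean 6.84), among them PSME2 and PSMC3. Mitochondrial ribosomal protein genes had 15 of 77 (random mean 10.5). Histone genes had 9 of 79 (random mean 10.8). Hardly any were found at 3 other families: 0 of 40 HOX genes, 1 of 55 keratin genes and 1 of 392 olfactory receptor genes, with random means of 5.46, 7.52 and 53.8. Random lists took no account of genes lying side by side, so members of a family that share a locus are not independent draws. Location was examined for ZNF genes alone. Transfer RNA genes, transcribed by RNA polymerase III, had an SP1 summit within 500 bases in 35 of 443 cases (7.90%), and in 17 of the 358 more than 2500 bases from a protein-coding gene end (4.75%, 2.99 to 7.47). By the same measure it was 11.4% of protein-coding, 5.19% of snRNA, 3.07% of lncRNA and 0.889% of miRNA genes. No random value was computed for these kinds.

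Of H3K27ac regions with 3 or more joined peaks there were 15. Apart from RGS20 and VMP1, those near named genes included regions in FMNL2 and nearest to ERRFI1 and KRT80, with ranks of 13, 15 and 26. An SP1 summit lay inside 8 of the 15, and inside 2 of the 6 that were not gene-distant.

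The first pattern is that SP1 and H3K27ac had their highest summits at the same positions, and a candidate explanation is sequence present in more copies than the assembly holds, which any library would enrich. Gene-distant positions are a rough stand-in that also takes in gene-poor DNA and the inside of long genes, such as the region in FMNL2. It may also miss multi-copy sequence closer to genes, since copy number was not measured. High shared summits outside it include those on chromosome 2 at 90398622 (SP1 54.0, H3K27ac 38.3) and on chromosome 8 at 85660220 (27.4 and 24.4). Gene-distant positions were defined after the highest summits had been seen at such places. Their share of 85.7% (70.6 to 93.7) among the 35 shared SP1 summits scoring over 10 in both lists thus largely restates that observation. That share leaves the explanation open. Within these 35, the scores of the 2 lists also ranked alike (Spearman's rho 0.918), against 0.103 in the other 99 shared summits. Like scores under 2 unrelated antibodies go with enrichment that any library would show. The 35 also span a wider range of scores, which can raise rho, so this does not decide the question. Of the other 99 shared summits 36.4% (27.6 to 46.2) were gene-distant, against 15.1% of all SP1 and 37.8% of all H3K27ac summits, which decides neither way. Binding of both at gene ends as the whole cause is argued against, since 14.2% (9.27 to 21.1) of shared SP1 summits lay there. This was less than the 44.1% of all SP1 summits but more than the 4.69% of all H3K27ac summits. Such binding as a part of the cause is therefore not excluded. SP1 at acetylated enhancers stays open for shared summits outside gene-distant positions, though these may still hold multi-copy sequence. The IgG library, which bears on this directly, was not analysed here.

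The second pattern is the small share of H3K27ac summits at gene ends, although the mark is known from active promoters. Dilution by calls near the threshold predicts a higher share among higher scores, but among H3K27ac summits without an SP1 partner the higher-scoring part minus the lower-scoring part was -0.901 percentage points (-2.34 to 0.534). Background that follows DNA copy number and mappability may contribute, since per 10-Mb bin these summits went with SP1 summits away from gene ends (Spearman's rho 0.741 over 316 bins, which are not independent replicates) more than with protein-coding genes (0.244). These H3K27ac summits lay in gene spans in 43.0% of cases against 42.6% by random placement. The SP1 summits they were set against did so in 48.4%, above every placement (up to 45.3%), and went with protein-coding genes at rho 0.496. That comparison set may thus hold more than background. Open chromatin common to both libraries would also give such a rho as 0.741, so this was not settled. H3K27ac summits without an SP1 partner were also clustered. Of 3068, 202 lay closer to another than the default distance at which ROSE joins peaks. In 100 placements that kept the number per Mb, 78 to 165 did (mean 126). Without gene-distant positions it was 111 of 1923, against 28 to 89. Summits at gene ends were included, so the clusters were not shown to be distal or to account for the small share there.

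The third pattern is that no SP1 summit was called in the H3K27ac region of RGS20, and SP1 signal there may lie below the calling threshold. The nearest called SP1 summit was 76287 bases from the region, and without coverage this explanation and a true lack of SP1 cannot be told apart. Such a lack was common: of 98 H3K27ac regions of 2 or more peaks, 27 held an SP1 summit (27.6%), and of the 47 that were not gene-distant, 14 did (29.8%). For the absence of a called SP1 summit in the H3K27ac region of RGS20, no biological explanation was tested, since the design holds 1 condition.

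A further hypothesis, written before its result was seen, was that mesenchymal genes and growth-signal transcription factor genes would have H3K27ac summits within 50 kb more often than other genes of their length. Gene-distant summits were left out. The mesenchymal list had 3 of 16 members with one (SNAI1, CAV1 and LOX), percentile 67.6 of random lists matched on length, which leaves the question open. The transcription factor list had 3 of 21 (RUNX1, SMAD3 and HMGA2), percentile 32.1 and below the random mean of 3.92, so the prediction failed. Of the other 13 lists, the highest was hepatocyte markers with 4 of 14 at percentile 94.5.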
